A study of Homo sapiens with 24 samples.

How the data were processed

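UCSD-AML1 and ELF-153 cells were grown in RPMI with 20% serum and 5 ng/ml GM-CSF, with or without 100 nM DAC renewed daily on 4 days. RNA of 3 libraries per group was sequenced in pairs on a HiSeq 2500 after ribosomal RNA depletion with a stranded kit. The labels call the libraries technical triplicates, so that p-values measure the spread between these libraries and not between independent experiments. The deposited values are signal: per library, reads per transcript (96 h and 144 h) or per repeat family (96 h) divided by a single size factor, scaled within each table. The submitters' notes name FastQC, TopHat2, STAR, HTSeq, DESeq2 and the build hg19 without versions, and the step each tool served is not given in the sources used here, so the tables of the 2 harvests may come from different aligners. Within a tolerance of 0.01, 100% of non-zero values in every library were whole multiples of its step, and dividing by the step recovered the reads. In 1 repeat column the step, 1.005, lay close to 1.

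Transcripts were summed to genes by GENCODE release 29 identifiers (GRCh38), used for names, biotypes, chromosomes and GC content, with no coordinates printed. Of 204940 transcripts 181859 (88.7%, holding 97.8% of the value) matched 52994 genes, and 23081 unmatched transcripts were tested on their own. Low values of shared transcripts (ACTB 622.4 reads in the mean at 96 h, 7.3 on its main coding transcript, and HBG2 0) point to reads counted only where unique to a transcript, so levels do not compare between genes and paralogs are uncertain. UHRF1, MAGEA2, CTAG1A, SSX4, CT45A1, BOP1, PECAM1, NESP55, HYMAI, CCL3, CCL4 and CCL5 had no matched transcript.

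The main test was limma 3.58.1 in R 4.3.3 (group means over the 12 libraries of a table, eBayes with trend and robust) on log2(gene sum + 1), for genes at 10 or more in at least 3 libraries, with Benjamini-Hochberg adjusted p at 0.05. The plan made before the data were examined named edgeR's quasi-likelihood test for raw counts; as the values are scaled, edgeR 4.0.16 on the recovered reads became an alternative. It called, higher and lower, 4203 and 2786 genes (UCSD-AML1, 96 h), 3354 and 2599 (ELF-153, 96 h), 4524 and 3320 (UCSD-AML1, 144 h) and 3364 and 3258 (ELF-153, 144 h). The plan left out the test between harvests where a table held no raw counts; it was run because the reads were recovered, over all 24 libraries, and compares changes only, never levels. Repeat reads were scaled by the size factors of the gene table. The 28 gene lists, repeat classes and chromosomes with at least 5 members were tested with camera (correlation 0.01) and with an estimated correlation, and the lists with fry; overlaps with Fisher's exact test, two-sided.

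Named genes followed a rule set in advance: a fixed set, the 8 largest rises and falls of each DAC effect, 4 near 0, the 4 list members with the smallest adjusted p, and 6 per direction for differences and repeats, left out for length in rank order or by list. Some genes selected by the rule are not reported here. A gene named in one comparison may have its levels in the other line beside it. For genes with 0 reads in a group the bound used a floor of 3 reads; for 1 to 3 reads a 95% counting interval was computed.

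Alternatives were edgeR with TMM or RLE, DESeq2 1.42.0, limma-voom, filters of 1 read or 1 CPM, a fold of 1.5, the 6 libraries of a line, a replicate block, TMM in limma, pseudocounts 0.5 and 8, sums without retained-intron and processed transcripts, the mitochondrial rRNA share as covariate, removal of each library's GC trend (loess span 0.3), other repeat scalings or a mean count of 50, and leaving out libraries. Untreated and treated libraries of the same number were paired only in UCSD-AML1 at 144 h by correlation across genes (0.13, 0.12 and 0.26 against −0.2 to 0.14 for other numbers); with that block 3366 genes were higher and 4627 lower. The chi-square per degree of freedom between replicates was 3.7 to 231.4, above counting error. In simulated data limma called at most 0.06% of unchanged genes and 1.19% of unchanged repeat families. It recovered 51.5% and 53% of 4-fold time differences and 89.6% and 89.6% of 2-fold repeat changes (UCSD-AML1 and ELF-153). With 66 or 67 changed per fold and noise shared by genes not examined, such rates may not hold for the real fits. Tables and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Transcript-level changes were not analysed here.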

Results

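The data are stranded, ribosomal-RNA-depleted total RNA sequencing of 2 human acute myeloid leukaemia cell lines, UCSD-AML1 and ELF-153, each cultured with or without decitabine (DAC). DAC is a cytidine analogue that enters DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. Cells were harvested 96 h or 144 h after the start of 4 daily doses of 100 nM DAC. Each of the 8 groups of line, treatment and time holds 3 libraries, labelled technical triplicates (24 in all). At 96 h reads of repeat families were also tabulated for the same 12 libraries.

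Depth is the number of reads assigned to transcripts, in Mreads (mega-reads), for replicates 1, 2 and 3. At 96 h, untreated UCSD-AML1 held 19.42, 21.33 and 23.9 and treated UCSD-AML1 25.75, 28.11 and 28.28. Untreated ELF-153 held 13.15, 16.64 and 17.76 and treated ELF-153 19.43, 24.25 and 20.6. At 144 h, untreated UCSD-AML1 held 22.71, 21.42 and 15.1 and treated UCSD-AML1 25.87, 23.89 and 15.17. Untreated ELF-153 held 25.54, 15.79 and 16.42 and treated ELF-153 20.22, 28.53 and 21.51. The repeat table held 1.91, 2.22 and 2.54 Mreads in untreated and 2.76, 2.42 and 2.88 in treated UCSD-AML1, and 2.45, 2.57 and 3.01 in untreated and 3.36, 3.55 and 3.17 in treated ELF-153. Of this table RN7SK, an RNA gene, took 20.3% to 33.9% in UCSD-AML1 and 45.9% to 60.7% in ELF-153; RNA genes were left out of the repeat tests and repeat-based scaling. Mitochondrial ribosomal RNA took 13.1% to 63.8% of the assigned reads over the libraries. In group means (± SD, n = 3) it went from 50.07 ± 1.08% to 62.87 ± 1.07% with DAC in UCSD-AML1 at 96 h and from 25.17 ± 11.12% to 43.43 ± 6.25% in ELF-153 at 96 h. At 144 h it went from 49.4 ± 4.25% to 51.17 ± 10.84% and from 24.3 ± 12.06% to 47 ± 5.79%.

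Levels below are gene sums of the deposited scaled reads, given as mean ± SD of 3 libraries, untreated first. Log2 changes are treated minus untreated on the log2(value + 1) scale, which understates genes with low levels, with their standard error, and stand in brackets after gene names. Adjusted p-values are limma's over all genes tested, and a gene is said to rise or fall only where that value lay below 0.05. Members of a gene list not counted as risen or fallen did not pass the test. For genes with 3 or fewer reads in the lower group a lower bound or a ratio of reads with its counting interval stands in place of the log2 change; bounds and intervals cover counting error only. Such genes, called near 0, are left out of the largest rises and falls with DAC.

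The first comparison asks which transcripts DAC changed in UCSD-AML1 at 96 h. Megakaryocyte and platelet genes rose: of 28 tested members, 25 rose (the same adjusted over the list alone; camera adjusted p = 1.47e-14). PF4, the platelet factor 4 gene, went from 157 ± 28.4 to 7200 ± 1440 (5.51 ± 0.33, adjusted p = 5.45e-08). THBS1, the gene of thrombospondin-1, rose (4.21 ± 0.19, adjusted p = 7.41e-09). Of 23 erythroid genes, 17 rose and 3 fell (18 higher and 3 lower adjusted over the list alone; camera adjusted p = 5.07e-07). GATA1, a transcription factor of the erythroid and megakaryocyte lineages, went from 400 ± 18.4 to 1630 ± 154 (2.03 ± 0.24, adjusted p = 1.85e-05), and the fetal globin gene HBG1 from 3.98 ± 0.739 to 189 ± 63.7 (5.20 ± 0.36, adjusted p = 1.79e-07). Of 44 cell cycle genes, 42 fell (the same adjusted over the list alone; camera adjusted p = 1.94e-25). CCNA2, the cyclin of S phase, went from 7030 ± 259 to 290 ± 56.4 (−4.61 ± 0.19, adjusted p = 4.84e-09).

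Of 20 cancer-testis antigens tested, genes normally restricted to germ cells, 16 rose (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.11e-09). The median log2 change was 3.36 (3.70 with members near 0 at their bound). MAGEC2 went from 0 ± 0 to 107 ± 6.14 and was at least 118-fold higher. MAGEB2, a member of the same MAGE family, went from 2.23 ± 1.73 to 95 ± 14.7 (5.01 ± 0.36, adjusted p = 2.2e-07). Of 15 germ-cell genes, 9 rose (the same adjusted over the list alone; camera adjusted p = 7.13e-06). The germ-cell RNA-binding gene DAZL went from 0 ± 0 to 139 ± 32.5 and was at least 152-fold higher. Of 24 targets of NF-kB and inflammatory signalling, 13 rose (15 higher adjusted over the list alone; camera adjusted p = 1.89e-06). TNFAIP3, a feedback inhibitor of NF-kB, went from 441 ± 16.5 to 2400 ± 418 (2.43 ± 0.18, adjusted p = 2.53e-07), and JUN rose (2.79 ± 0.20, adjusted p = 2.43e-07). Of 31 genes of ribosome biogenesis and MYC targets, 23 fell (the same adjusted over the list alone; camera adjusted p = 6.79e-08). MRTO4, a ribosome assembly factor, fell (−1.68 ± 0.17, adjusted p = 4.52e-06). Of 42 replication-dependent histone genes, 9 rose and 26 fell (9 higher and 27 lower adjusted over the list alone; camera adjusted p = 2.39e-06, and 0.259 with an estimated correlation). The linker histone gene HIST1H1B went from 55900 ± 6710 to 3790 ± 863 (−3.90 ± 0.21, adjusted p = 2.51e-08). Of 22 imprinted genes, 11 rose and 1 fell (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00456, and 0.061 with an estimated correlation). The imprinted antisense transcript KCNQ1OT1 rose (2.32 ± 0.16, adjusted p = 1.52e-07). Of 46 interferon-stimulated genes, 4 rose and 13 fell (4 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.0211, and 0.297 with an estimated correlation). The antiviral gene OAS2 went from 7070 ± 409 to 2510 ± 170 (−1.49 ± 0.17, adjusted p = 1.16e-05).

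Of the genes named in advance, DNMT1, the maintenance DNA methyltransferase (−1.12 ± 0.19, adjusted p = 0.000321), DNMT3B, a de novo DNA methyltransferase (−1.98 ± 0.42, adjusted p = 0.00211), MECOM, the EVI1 transcription factor gene (−1.12 ± 0.37, adjusted p = 0.0278) and KIT, the stem cell factor receptor (−2.32 ± 0.46, adjusted p = 0.0013) fell. CDKN1A, the p21 cell cycle inhibitor (2.36 ± 0.40, adjusted p = 0.000394) rose. The log2 change did not pass the test for DNMT3A (−0.14 ± 0.23), CD34 (−0.03 ± 0.21), GATA2 (0.04 ± 0.15) and MYC (−0.47 ± 0.32), with adjusted p from 0.271 to 0.936. CDKN2B went from 0 ± 0 to 0.324 ± 0.561 scaled reads (adjusted p = 0.657). Genes near 0 apart, C3, a complement component (7.76 ± 0.38, adjusted p = 1.29e-08), the erythroid transcription factor gene KLF1 (7.58 ± 0.40, adjusted p = 2.45e-08) and the endogenous retroviral envelope gene ERV3-1 (6.90 ± 0.33, adjusted p = 1.12e-08) rose most. WDR76 fell most (−5.63 ± 0.38, adjusted p = 1.48e-07). Of 17609 genes tested, 3513 were higher and 3545 lower, of which 2659 and 2523 differed at least 2-fold. Of 2566 processed pseudogenes 728 fell and 177 rose. In edgeR with TMM the median of all genes moved by 0.15, and 60.1% of called genes were higher against 49.8% in limma.

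The same question was asked of UCSD-AML1 at 144 h. Of 28 megakaryocyte and platelet genes, 22 rose (23 higher adjusted over the list alone; camera adjusted p = 1.59e-11). THBS1 went from 263 ± 41.7 to 10500 ± 1850 (5.31 ± 0.18, adjusted p = 1.19e-09). Of 23 erythroid genes, 15 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 8.25e-07). HBG1 went from 3.19 ± 2.55 to 320 ± 71.5 (6.42 ± 0.53, adjusted p = 2.27e-06) and GATA1 rose (1.83 ± 0.33, adjusted p = 0.000778). Of 43 cell cycle genes, 39 fell (40 lower adjusted over the list alone; camera adjusted p = 6.43e-19). CCNA2 went from 5380 ± 1480 to 119 ± 24.6 (−5.47 ± 0.29, adjusted p = 4.54e-08). Of 46 interferon-stimulated genes, 27 fell (the same adjusted over the list alone; camera adjusted p = 4.78e-06, and 0.161 with an estimated correlation). OASL went from 842 ± 35.2 to 182 ± 33.2 (−2.22 ± 0.19, adjusted p = 2.19e-06). With TMM scaling 2 of the 46 rose and 22 fell.

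Of 21 cancer-testis antigens, 16 rose (the same adjusted over the list alone; camera adjusted p = 1.01e-08). The median log2 change was 2.87 (3.60 with members near 0 at their bound). MAGEC2 went from 0 ± 0 to 126 ± 25.9 and was at least 124-fold higher. Of 14 germ-cell genes, 9 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.000111, and 0.0572 with an estimated correlation). DAZL was at least 116-fold higher. Of 24 NF-kB and inflammatory targets, 16 rose and 1 fell (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.36e-08). TNFAIP3 went from 720 ± 161 to 4270 ± 450 (2.59 ± 0.17, adjusted p = 2.47e-07). Of 31 ribosome biogenesis and MYC targets, 1 rose and 21 fell (1 higher and 22 lower adjusted over the list alone; camera adjusted p = 0.000255). Of 44 histone genes, 8 rose and 28 fell (8 higher and 29 lower adjusted over the list alone; camera adjusted p = 4.78e-06, and 0.175 with an estimated correlation). Of 23 imprinted genes, 10 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.0378, and 0.123 with an estimated correlation). KCNQ1OT1 rose (2.82 ± 0.22, adjusted p = 9.58e-07).

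Of the genes named in advance, DNMT1 (−0.69 ± 0.23, adjusted p = 0.0247), DNMT3B (−1.88 ± 0.42, adjusted p = 0.00288), MECOM (−1.52 ± 0.24, adjusted p = 0.000226), CD34, a progenitor surface marker (−1.02 ± 0.21, adjusted p = 0.00149) and KIT (−3.20 ± 0.55, adjusted p = 0.000609) fell. CDKN1A (1.82 ± 0.43, adjusted p = 0.00425) rose. The log2 change did not pass the test for DNMT3A (−0.54 ± 0.25), GATA2 (0.12 ± 0.15) and MYC (0.12 ± 0.22), with adjusted p from 0.0898 to 0.684. CDKN2B went from 0 ± 0 to 1.13 ± 1.28 scaled reads (adjusted p = 0.142). Genes near 0 apart, CSF1, a macrophage growth factor, rose most after HBG1 (6.17 ± 0.62, adjusted p = 8.05e-06) and the spindle gene ASPM fell most (−6.33 ± 1.07, adjusted p = 0.000525). Of 17180 genes tested, 3450 were higher and 4609 lower, of which 2627 and 3559 differed at least 2-fold. Of 2477 processed pseudogenes 1222 fell and 143 rose. In edgeR with TMM the median of all genes moved by 0.28, and 57.7% of called genes were higher against 42.8% in limma.

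In ELF-153 at 96 h interferon-stimulated, megakaryocyte and germ-cell genes rose and cell cycle genes fell. Of 46 interferon-stimulated genes, 41 rose (43 higher adjusted over the list alone; camera adjusted p = 1.22e-20). RSAD2, which encodes the antiviral enzyme viperin, went from 165 ± 33.1 to 3750 ± 198 (4.51 ± 0.18, adjusted p = 4.99e-10). IFI44L rose (7.34 ± 0.28, adjusted p = 3.92e-10). Of 28 megakaryocyte and platelet genes, 19 rose (20 higher adjusted over the list alone; camera adjusted p = 1.66e-10). ITGB3, an integrin subunit gene, went from 41.3 ± 7.3 to 1280 ± 209 (4.92 ± 0.17, adjusted p = 1.58e-10) and TUBB1, the platelet beta-tubulin gene, rose (6.74 ± 0.19, adjusted p = 1.86e-11). Of 23 erythroid genes, 17 rose (the same adjusted over the list alone; camera adjusted p = 3.27e-10). GATA1 went from 32.5 ± 14.6 to 980 ± 113 (4.95 ± 0.24, adjusted p = 3.1e-09) and HBG1 from 4.48 ± 1.96 to 1990 ± 881 (8.47 ± 0.36, adjusted p = 1.06e-09). Of 20 cancer-testis antigens, 19 rose (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.72e-18). The median log2 change was 6.67 (6.67 with members near 0 at their bound). MAGEB2 was at least 788-fold higher. Of 15 germ-cell genes tested among 41 matched, 15 rose (the same adjusted over the list alone, camera adjusted p = 1.12e-13). The filter in part sets this share. DAZL was at least 730-fold higher, and TDRD12, of the germ-cell transposon silencing pathway, went from 2 ± 0.88 to 690 ± 19.9 (7.89 ± 0.36, adjusted p = 1.75e-09).

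Of 44 cell cycle genes, 32 fell (34 lower adjusted over the list alone; camera adjusted p = 7.58e-19). The replication gene GINS2 went from 4400 ± 461 to 635 ± 57.1 (−2.79 ± 0.18, adjusted p = 6.62e-08). Of 24 NF-kB and inflammatory targets, 22 rose (23 higher adjusted over the list alone; camera adjusted p = 7.94e-11). CXCL8, the interleukin-8 gene, went from 235 ± 99.4 to 5300 ± 2520 (4.50 ± 0.41, adjusted p = 1.83e-06) and TNFAIP3 rose (1.99 ± 0.18, adjusted p = 1.43e-06). Of 31 ribosome biogenesis and MYC targets, 12 fell (13 lower adjusted over the list alone; camera adjusted p = 1.82e-05). Of 42 histone genes, 12 rose and 26 fell (the same adjusted over the list alone; camera adjusted p = 2.11e-06, and 0.233 with an estimated correlation). HIST1H1T, a testis linker histone gene, rose (6.69 ± 0.23, adjusted p = 1.58e-10). Of 22 imprinted genes, 9 rose (10 higher adjusted over the list alone; camera adjusted p = 0.00166), a call that held with an estimated correlation (adjusted p = 0.0447). The paternally expressed gene MKRN3 had a ratio of 514 (counting interval 91.9 to 20300).

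Of the genes named in advance, DNMT1 (−1.27 ± 0.19, adjusted p = 0.000136), DNMT3B (−2.59 ± 0.42, adjusted p = 0.000339) and CD34 (−0.85 ± 0.21, adjusted p = 0.00669) fell. CDKN1A (1.70 ± 0.40, adjusted p = 0.00485) rose. CDKN2B, the p15 cell cycle inhibitor, had a ratio of 260 (counting interval 71.7 to 2150). The log2 change did not pass the test for DNMT3A (0.50 ± 0.23), MECOM (0.75 ± 0.37), KIT (0.64 ± 0.46), GATA2 (0.33 ± 0.15) and MYC (−0.87 ± 0.32), with adjusted p from 0.0518 to 0.304. Genes near 0 apart, HIST1H4B, a histone H4 gene with near-identical paralogs (10.16 ± 0.61, adjusted p = 3.1e-08), HBG1 and TDRD12 rose most and ARHGEF16 fell most (−5.10 ± 0.63, adjusted p = 2.96e-05). Of 17609 genes tested, 3642 were higher and 2271 lower, of which 2796 and 1375 differed at least 2-fold. With the mitochondrial rRNA share as covariate (the mitochondrial covariate below) 2124 were higher and 1346 lower, and KIT was −1.12 (adjusted p = 0.054). Of called genes 61.6% were higher, and 52.8% to 58% under the alternatives that rescaled the libraries. Of 2566 processed pseudogenes 345 fell and 311 rose.

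In ELF-153 at 144 h the groups that had risen at 96 h were again higher. Of 46 interferon-stimulated genes, 42 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 1.3e-21). RSAD2 went from 115 ± 18.3 to 6210 ± 1050 (5.74 ± 0.19, adjusted p = 4.95e-10). IFI44L had a ratio of 1690 (counting interval 580 to 8220). Of 28 megakaryocyte and platelet genes, 20 rose (21 higher adjusted over the list alone; camera adjusted p = 2.31e-13). ITGB3 went from 35.8 ± 3.6 to 3150 ± 165 (6.42 ± 0.14, adjusted p = 1.34e-11). Of 23 erythroid genes, 18 rose (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.28e-10). GATA1 went from 32.9 ± 16.4 to 1170 ± 137 (5.22 ± 0.33, adjusted p = 1.15e-07) and HBG1 from 8.92 ± 6.31 to 6890 ± 1370 (9.69 ± 0.53, adjusted p = 4.78e-08). Of 21 cancer-testis antigens, 20 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 3.28e-16). The median log2 change was 6.79 (6.77 with members near 0 at their bound). MAGEB2 had a ratio of 2100 (counting interval 376 to 82800) and MAGEC2 was at least 198-fold higher. Of 14 germ-cell genes, 13 rose (14 higher adjusted over the list alone; camera adjusted p = 4.34e-12). DAZL was at least 615-fold higher.

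Of 43 cell cycle genes, 33 fell (36 lower adjusted over the list alone; camera adjusted p = 1.24e-14). GINS2 went from 5130 ± 806 to 459 ± 7.56 (−3.47 ± 0.16, adjusted p = 5.56e-09). Of 24 NF-kB and inflammatory targets, 21 rose (23 higher adjusted over the list alone; camera adjusted p = 2.59e-11). CXCL8 rose (5.11 ± 0.43, adjusted p = 1.66e-06), as did NFKBIA, which encodes an inhibitor of NF-kB (1.80 ± 0.15, adjusted p = 9.6e-07). Of 31 ribosome biogenesis and MYC targets, 18 fell (19 lower adjusted over the list alone; camera adjusted p = 2.3e-06). Of 44 histone genes, 13 rose and 25 fell (13 higher and 26 lower adjusted over the list alone; camera adjusted p = 0.0001, and 0.222 with an estimated correlation). HIST1H1B fell (−3.76 ± 0.22, adjusted p = 4.87e-08) and HIST1H2BF rose (5.28 ± 0.28, adjusted p = 2.52e-08). Of 23 imprinted genes, 11 rose (12 higher adjusted over the list alone; camera adjusted p = 0.000102), a call that held with an estimated correlation (adjusted p = 0.00986). NDN was at least 35.4-fold higher.

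Of the genes named in advance, DNMT1 (−0.93 ± 0.23, adjusted p = 0.00608), DNMT3B (−2.83 ± 0.42, adjusted p = 0.000161), CD34 (−1.52 ± 0.21, adjusted p = 7.46e-05) and MYC, a growth transcription factor (−1.22 ± 0.22, adjusted p = 0.000794) fell. CDKN1A (2.53 ± 0.43, adjusted p = 0.000475) rose. CDKN2B had a ratio of 228 (counting interval 62.6 to 1890), and MECOM a ratio of 37.8 (counting interval 6.37 to 1530). The log2 change did not pass the test for DNMT3A (0.53 ± 0.25), KIT (0.34 ± 0.55) and GATA2 (0.03 ± 0.15), with adjusted p from 0.107 to 0.914. With the mitochondrial covariate KIT was −1.59 (adjusted p = 0.00177), and without the library of each group farthest in that share (the far libraries below) it was 0.62 and passed. Genes near 0 apart, PF4 rose most after HBG1 (9.61 ± 0.42, adjusted p = 8.11e-09) and ARHGEF16 fell most (−4.84 ± 0.50, adjusted p = 7.11e-06). Of 17180 genes tested, 3567 were higher and 3124 lower, of which 2908 and 2120 differed at least 2-fold. Of called genes 53.3% were higher, 50.8% to 52.8% on rescaling and 46.7% with the mitochondrial covariate. Of 2477 processed pseudogenes 672 fell and 192 rose.

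**Figure D1:**
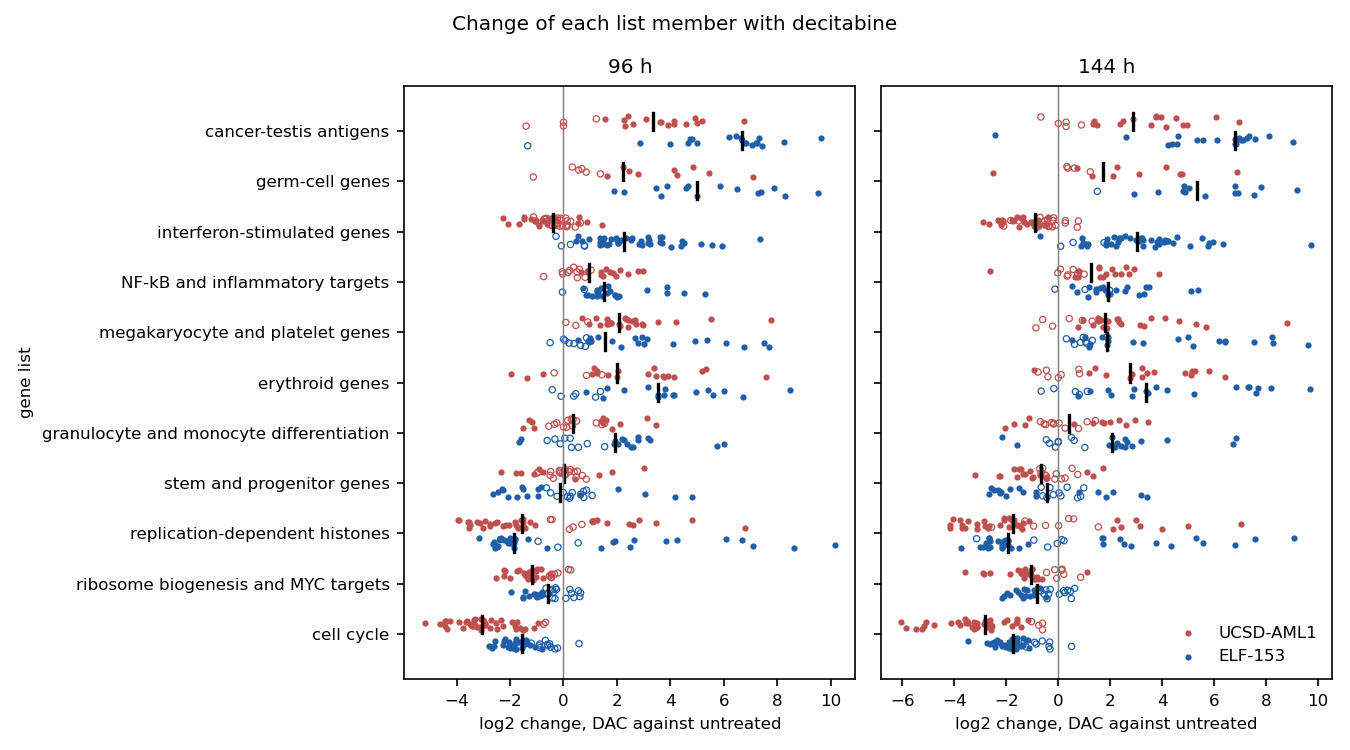
Log2 change with DAC of every tested member of 11 gene lists (x axis, log2 of treated over untreated on the value + 1 scale), at 96 h and 144 h in separate panels, for UCSD-AML1 in red and ELF-153 in blue. Filled points passed the limma test, and black bars are medians.

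**Figure D2:**
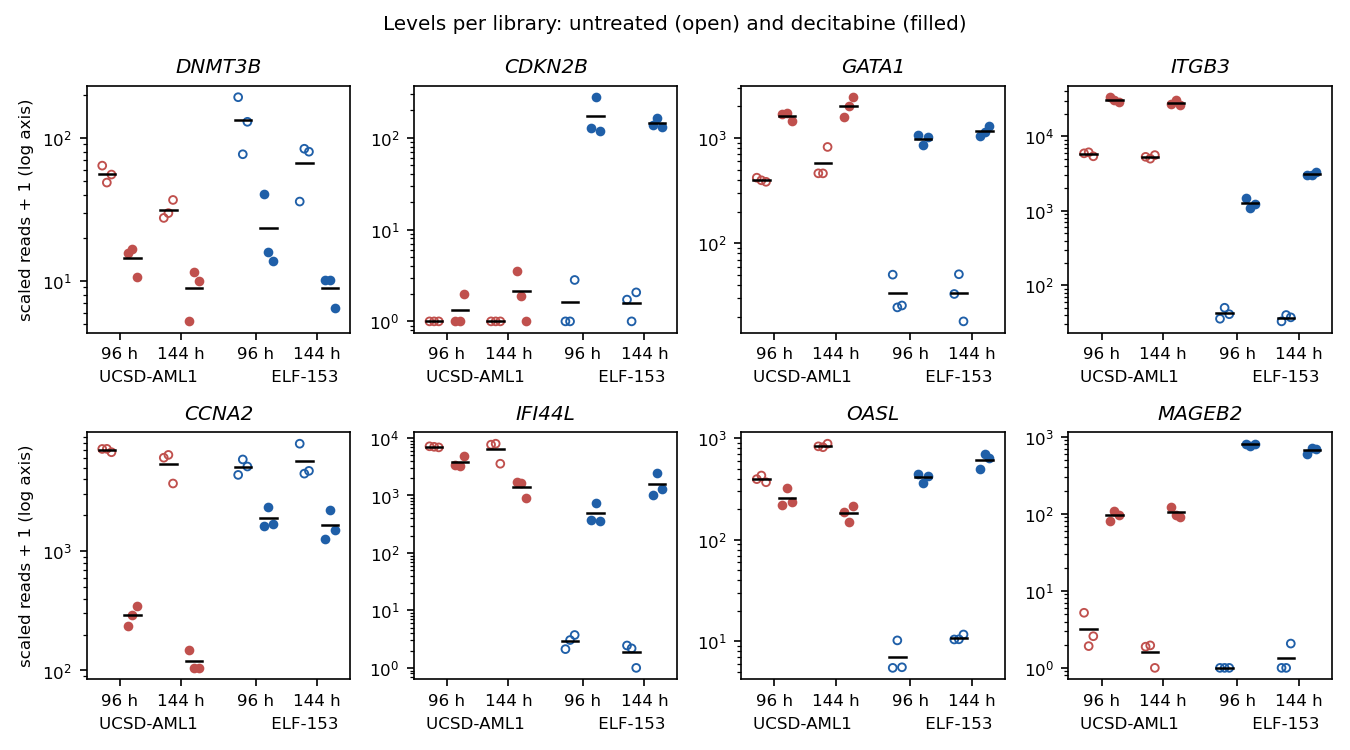
Scaled reads + 1 (log axis) of 8 genes in each library, untreated as open and DAC-treated as filled points, with bars at the mean of 3 libraries.

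For the remaining lists, counts are given in the order UCSD-AML1 at 96 h, ELF-153 at 96 h, UCSD-AML1 at 144 h and ELF-153 at 144 h. Of 32 p53 targets, 15, 12, 9 and 16 rose and 2, 1, 5 and 1 fell, and 15, 13, 9 and 17 and 2, 1, 5 and 2 adjusted over the list alone. In UCSD-AML1 at 96 h, ELF-153 at 96 h and ELF-153 at 144 h they were up by camera (adjusted p = 0.0108, 0.0175 and 0.00205, and 0.061, 0.0604 and 0.0137 with an estimated correlation). Of 27 apoptosis regulators, 11, 14, 11 and 14 rose and 3, 1, 4 and 3 fell, and 11, 14, 11 and 17 and 3, 2, 4 and 3 adjusted over the list alone. Camera had them up in UCSD-AML1 at 96 h, ELF-153 at 96 h and ELF-153 at 144 h (adjusted p = 0.0446, 0.00376 and 0.00104, and 0.0934, 0.0292 and 0.0117 with an estimated correlation). Of 25 (96 h) or 24 (144 h) granulocyte and monocyte differentiation genes, 8, 14, 9 and 14 rose and 4, 2, 4 and 2 fell, and 8, 15, 9 and 15 and 4, 2, 4 and 2 adjusted over the list alone. In ELF-153 at 96 h and ELF-153 at 144 h they were up by camera (adjusted p = 0.00118 and 0.00108, and 0.0589 and 0.114 with an estimated correlation). Of 30 (96 h) or 29 (144 h) stem and progenitor genes, 4, 5, 3 and 6 rose and 6, 12, 14 and 12 fell, and 4, 5, 3 and 6 and 6, 12, 14 and 14 adjusted over the list alone. Camera had them down in ELF-153 at 144 h (adjusted p = 0.0383, and 0.135 with an estimated correlation). HOXA7 fell in UCSD-AML1 (−1.79 ± 0.20, adjusted p = 1.14e-05) and HOXA5 in ELF-153 (−2.08 ± 0.19, adjusted p = 2.01e-06) at 96 h. Of 19 immune checkpoint and NK ligand genes, 8, 10, 6 and 7 rose and 1, 2, 3 and 2 fell, and 8, 10, 6 and 8 and 1, 2, 3 and 3 adjusted over the list alone. In UCSD-AML1 at 96 h they were up by camera (adjusted p = 0.016, and 0.061 with an estimated correlation). Of 8 B cell markers, 1, 1, 1 and 1 rose and 5, 4, 6 and 4 fell, the same adjusted over the list alone. Camera had them down in ELF-153 at 96 h, UCSD-AML1 at 144 h and ELF-153 at 144 h (adjusted p = 0.0199, 0.0494 and 0.0296, and 0.0604, 0.161 and 0.114 with an estimated correlation). Of 12 (96 h) or 10 (144 h) T and NK cell markers, 5, 4, 2 and 6 rose and 1, 0, 2 and 0 fell, and 5, 5, 2 and 6 and 1, 0, 2 and 0 adjusted over the list alone. In ELF-153 at 144 h they were up by camera (adjusted p = 0.0103, and 0.0651 with an estimated correlation).

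Of 22 genes of the DNA methylation machinery, 4, 4, 2 and 3 rose and 11, 6, 12 and 8 fell, and 5, 5, 2 and 5 and 13, 6, 12 and 8 adjusted over the list alone. Camera had them down in UCSD-AML1 at 96 h (adjusted p = 0.0446, and 0.155 with an estimated correlation). HELLS, a chromatin remodeller needed for methylation, fell in UCSD-AML1 at 96 h (−4.82 ± 0.28, adjusted p = 3.99e-08). Of 12 (96 h) or 13 (144 h) genes of decitabine uptake and metabolism, 1, 3, 0 and 2 rose and 5, 5, 5 and 4 fell, and 1, 3, 0 and 2 and 5, 5, 4 and 4 adjusted over the list alone. In UCSD-AML1 at 96 h they were down by camera (adjusted p = 0.0234, and 0.0697 with an estimated correlation). SAMHD1, a deoxynucleotide hydrolase, fell in UCSD-AML1 (−0.70 ± 0.16, adjusted p = 0.00348) and rose in ELF-153 (1.74 ± 0.16, adjusted p = 2.1e-06) at 96 h. Of 13 tumour suppressor genes hypermethylated in AML, 6, 5, 7 and 6 rose and 2, 3, 2 and 3 fell, and 6, 5, 8 and 6 and 2, 3, 3 and 3 adjusted over the list alone. Camera had them up in UCSD-AML1 at 144 h (adjusted p = 0.0395, and 0.175 with an estimated correlation). Of 9 (96 h) or 11 (144 h) fibroblast, epithelial and endothelial markers, 5, 3, 7 and 3 rose and 1, 1, 1 and 2 fell, and 6, 3, 7 and 4 and 1, 1, 1 and 3 adjusted over the list alone. In UCSD-AML1 at 144 h they were up by camera (adjusted p = 0.0478, and 0.211 with an estimated correlation). Of 4 (96 h) or 5 (144 h) beta protocadherin genes, 2, 1, 2 and 2 rose and 0, 0, 0 and 0 fell, and 2, 0, 2 and 2 and 0, 0, 0 and 0 adjusted over the list alone. Camera had them up in UCSD-AML1 at 144 h (adjusted p = 0.0478, and 0.149 with an estimated correlation). Of 436 (96 h) or 430 (144 h) zinc finger genes with a ZNF name, 88, 92, 81 and 78 rose and 39, 27, 59 and 38 fell, and 81, 84, 74 and 64 and 31, 26, 51 and 29 adjusted over the list alone. In UCSD-AML1 at 96 h they were up by camera (adjusted p = 0.0446, and 0.297 with an estimated correlation). Of 12 genes of double-stranded RNA sensing, 1, 7, 3 and 6 rose and 3, 1, 4 and 2 fell, and 1, 8, 3 and 6 and 2, 1, 4 and 2 adjusted over the list alone. Of 11 HLA class I antigen presentation genes, 1, 3, 1 and 4 rose and 3, 0, 2 and 0 fell, the same adjusted over the list alone. Of 5 HLA class II antigen presentation genes, 0, 1, 0 and 1 rose and 3, 1, 3 and 2 fell, and 0, 1, 0 and 1 and 3, 3, 3 and 3 adjusted over the list alone. Of 6 primary granule genes, 2, 3, 1 and 2 rose and 1, 2, 1 and 2 fell, and 2, 4, 1 and 2 and 1, 2, 1 and 2 adjusted over the list alone. Of 17 heat shock and unfolded protein response genes, 2, 3, 2 and 4 rose and 6, 3, 6 and 4 fell, and 2, 3, 2 and 4 and 6, 3, 6 and 5 adjusted over the list alone.

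For some lists the median log2 change, the mean and the direction of camera differed in sign. The median and mean were −0.05 and 0.06 with camera down for the DNA methylation machinery in ELF-153 at 96 h, and 0.18 and 0.07 with camera down at 144 h. They were −0.24 and 0.44 with camera up for HLA class I and −0.09 and 1.07 with camera up for beta protocadherins in ELF-153 at 144 h. They were 0.77 and 0.33 with camera down for fibroblast, epithelial and endothelial markers and −0.11 and 0.05 with camera down for heat shock genes in ELF-153 at 96 h, and −0.33 and 0.00 with camera up for T and NK cell markers in UCSD-AML1 at 144 h. In UCSD-AML1 at 96 h the median of heat shock genes went from −0.12 to 0.03 with TMM scaling, and after removing the trend with GC content the medians of double-stranded RNA sensing went from −0.15 to 0.02 and of HLA class I from 0.15 to −0.01. The median of ZNF genes in ELF-153 went from 0.26 to −0.07 at 96 h and from 0.22 to −0.01 at 144 h after that correction, which moved the median of all genes there by −0.17 at 96 h; with the mitochondrial covariate it moved by −0.17 and −0.21. Across genes, which are not independent replicates, the Spearman correlation of the log2 change with GC content was 0.242 in UCSD-AML1 and −0.304 in ELF-153 at 96 h, and 0.333 and −0.214 at 144 h.

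Shared responses were sought by overlap of the called genes. At 96 h 1579 genes were higher in both lines against 726.6 given by chance (odds ratio 4.76), and 1087 were lower in both against 457.2 (odds ratio 4.81). At 144 h the counts were 1652 against 716.3 (odds ratio 5.67) and 1598 against 838.1 (odds ratio 3.84). Genes that went opposite ways numbered 127 and 253 at 96 h and 130 and 267 at 144 h, higher and lower in UCSD-AML1. Across genes, log2 changes of the lines correlated with Pearson's r of 0.45 at 96 h and 0.433 at 144 h. Between times, 2437 genes were higher and 2891 lower at both in UCSD-AML1 (r = 0.882 across genes), and 2568 and 1843 in ELF-153 (r = 0.917).

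The line difference in response to DAC was tested as the ELF-153 change minus the UCSD-AML1 change. For interferon-stimulated genes the difference was positive for 42 of 46 members at 96 h (43 adjusted over the list alone), with a median of 2.70 (camera adjusted p = 1.46e-25). At 144 h it was positive for 45 of 46, with a median of 3.92 (camera adjusted p = 2.29e-30). For RSAD2 the difference at 96 h was 3.92 ± 0.25, adjusted p = 3.59e-07. IFI44L went from 7030 ± 153 to 3800 ± 911 in UCSD-AML1 and from 1.97 ± 0.81 to 495 ± 217 in ELF-153 at 96 h (difference 8.25 ± 0.40, adjusted p = 1.69e-08). Cancer-testis antigens had a positive difference in 16 of 20 members at 96 h (17 adjusted over the list alone; camera adjusted p = 1.82e-08) and 17 of 21 at 144 h (camera adjusted p = 5.36e-08), and germ-cell genes in 11 of 15 (13 adjusted over the list alone; camera adjusted p = 7.36e-07) and 13 of 14 (14; camera adjusted p = 4.04e-07). Cell cycle genes, which fell in both lines, fell less in ELF-153, with a positive difference in 24 of 44 members at 96 h (26 adjusted over the list alone; camera adjusted p = 8.67e-08) and 19 of 43 at 144 h (22; camera adjusted p = 5.25e-05), or 12 higher and 1 lower there with TMM scaling. T and NK cell markers were called at 144 h, with 7 higher and 1 lower of 10, the same counts adjusted over the list alone (camera adjusted p = 0.0411, and 0.186 with an estimated correlation). The calls of the other 4 lists held with an estimated correlation at both times.

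GATA1 rose in both lines with a larger change in ELF-153 at 96 h (difference 2.92 ± 0.34, adjusted p = 7.44e-05) and 144 h (3.39 ± 0.47, adjusted p = 0.000389), as did HBG1 (3.26 ± 0.51, adjusted p = 0.000707 and 3.27 ± 0.75, adjusted p = 0.00904). The difference for KIT, which fell in UCSD-AML1, was 2.97 ± 0.65, adjusted p = 0.00605 at 96 h and 3.54 ± 0.78, adjusted p = 0.00757 at 144 h and passed at both with the mitochondrial covariate. At 144 h the differences for MYC (−1.34 ± 0.32, adjusted p = 0.00941) and DNMT3A (1.07 ± 0.35, adjusted p = 0.0364) passed the test. The difference for CDKN2B, near 0 in a group, passed at 96 h (adjusted p = 7.34e-05). The largest positive differences were of HIST1H4C (9.60 ± 0.47, adjusted p = 1.69e-08) and IFI44L at 96 h and at 144 h of IFI44L, whose ELF-153 level was near 0 without DAC (adjusted p = 2.24e-07). The most negative were of genes near 0 in a group. SYNDIG1 went from 0.611 ± 1.06 to 36.6 ± 3.34 in UCSD-AML1 and from 571 ± 96.1 to 87.9 ± 13.9 in ELF-153 at 96 h (adjusted p = 7.61e-07). Of 17609 genes at 96 h 3011 had a positive and 1533 a negative difference, and of 17180 at 144 h 3420 and 1741. Leaving out 1 library (named in brackets) gave 2008 (ELF-153 DAC 2) to 4513 (ELF-153 untreated 1) positive and 1033 (ELF-153 untreated 2) to 2478 (ELF-153 untreated 1) negative differences at 144 h, and the mitochondrial covariate 1734 and 755. Counts at 96 h, then 144 h, were 1984 and 1897, then 1961 and 2533, in edgeR with TMM, 1855 and 823, then 4992 and 2795, without the far libraries and 1991 and 1734, then 2532 and 2114, after GC trend removal. The split moved with scaling: 66.3% of called differences were positive in limma at both times, and 43.6% to 54.5% under the alternatives that rescaled the libraries. Those alternatives shifted the median difference of all genes by −0.19 to −0.33.

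As background the untreated lines were compared, as ELF-153 minus UCSD-AML1. MECOM, the EVI1 gene, stood at 4000 ± 80.3 scaled reads in UCSD-AML1 and 1.63 ± 1.55 in ELF-153 at 96 h (adjusted p = 3.38e-11). At 144 h the levels had a ratio of 11000 (counting interval 1980 to 435000) in favour of UCSD-AML1. IFI44L (−11.25 ± 0.28, adjusted p = 1.9e-12) was lower in ELF-153 at 96 h. PAG1 (10.01 ± 0.21, adjusted p = 4.21e-13) was higher. At 144 h PAG1 (9.92 ± 0.33, adjusted p = 1.34e-10) was higher and the scavenger receptor gene STAB1 (−10.34 ± 0.54, adjusted p = 1.42e-08) lower. At 96 h untreated ELF-153 held less GATA1 (−3.66 ± 0.24, adjusted p = 2.16e-08), KIT (−2.74 ± 0.46, adjusted p = 0.000201) and CDKN1A (−2.40 ± 0.40, adjusted p = 0.000179), and more DNMT1 (0.83 ± 0.19, adjusted p = 0.00167) and GATA2 (0.98 ± 0.15, adjusted p = 7.68e-05). Of 17609 genes at 96 h 4003 were higher and 6192 lower in ELF-153, and of 17180 at 144 h 4934 and 3969. With the mitochondrial covariate the counts were 1880 and 2624 at 96 h and 3508 and 2237 at 144 h, or 3015 and 2510 there with a replicate block. At 96 h 39.3% of called genes were higher in limma and 50.2% to 52% under the alternatives that rescaled the libraries, which shifted the median of all genes by 0.25 to 0.29.

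Harvests were compared as the change at 144 h minus that at 96 h. In UCSD-AML1, CHAC1, a glutathione-degrading gene of the stress response, went from 15.6 ± 0.914 to 65.3 ± 21.6 at 96 h (1.94) and from 200 ± 21.2 to 40.5 ± 4.88 at 144 h (−2.28; difference −4.21 ± 0.38, adjusted p = 3.26e-06). SLC7A11, the cystine transporter gene, went from 320 ± 43.1 to 178 ± 38.8 at 96 h (−0.86) and from 1970 ± 696 to 132 ± 26.7 at 144 h (−3.83; difference −2.97 ± 0.41, adjusted p = 0.00232), and ULBP1, a ligand of the NK receptor NKG2D, went from 3.89 ± 3.42 to 26.8 ± 4.15 at 96 h (2.94) and from 58.3 ± 21.3 to 20.6 ± 1.83 at 144 h (−1.39; difference −4.33 ± 0.69, adjusted p = 0.0111). Levels are comparable only within a harvest. Untreated levels of these 3 genes still moved more between harvests than treated ones, so changed untreated cultures stay open. SIK1, whose treated level moved more, had a positive difference (1.91 ± 0.34, adjusted p = 0.0184) that did not pass with a replicate block. In ELF-153, THBS1 went from 59.7 ± 11.3 to 1020 ± 75.1 at 96 h (4.09) and from 35.9 ± 3.78 to 2660 ± 212 at 144 h (6.17; difference 2.09 ± 0.25, adjusted p = 0.000344). F2RL2 went from 3.2 ± 2.35 to 37.4 ± 10.6 scaled reads at 96 h and from 0.242 ± 0.419 to 85.4 ± 27.4 at 144 h (adjusted p = 0.0241). MECOM went from 1.63 ± 1.55 to 2.8 ± 0.164 scaled reads at 96 h and from 0.242 ± 0.419 to 12 ± 1.68 at 144 h (adjusted p = 0.0207). Of 18544 genes tested 7 had a higher and 13 a lower change at 144 h in UCSD-AML1, with 1679 at an unadjusted p under 0.05; TMM scaling moved the median of all genes by 0.14. In ELF-153 8 had a higher and 0 a lower change, with 1114 at an unadjusted p under 0.05. Higher and lower counts in UCSD-AML1, then ELF-153, were 5 and 8, then 7 and 0, in edgeR, 29 and 40, then 23 and 0, in DESeq2, 11 and 9, then 9 and 0, with TMM scaling, 0 and 3, then 2 and 0, with a replicate block (without F2RL2 and MECOM), 24 and 152, then 41 and 21, with the mitochondrial covariate, 42 and 249, then 690 and 666, without the far libraries and 22 and 41, then 19 and 3, after removal of each library's GC trend. Leaving out 1 library gave as few as 0 higher and 3 lower genes in UCSD-AML1 and 4 to 14 higher in ELF-153.

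Repeat transcripts, many silenced by DNA methylation, were compared at 96 h on the gene-table scale. All 10 LTR12/HERV9 families rose in UCSD-AML1 and 9 of 10 in ELF-153, with median log2 changes of 2.35 and 1.93. Their summed reads went from 4354 ± 104 to 18270 ± 1555 in UCSD-AML1 and from 3776 ± 224 to 12531 ± 468 in ELF-153, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Camera gave adjusted p = 3.72e-08 and 2.1e-10 for this class, and 0.194 and 0.111 with an estimated correlation; no class call in the gene-table scaling held with an estimated correlation. On scaling factors from the repeats alone the medians were 1.97 and 1.43, with 8 and 7 families higher. LTR12C, long terminal repeats of the endogenous retrovirus HERV9, went from 2660 ± 71.5 to 8860 ± 906 (1.73 ± 0.13, adjusted p = 6.57e-07) in UCSD-AML1 and from 2400 ± 16.5 to 7120 ± 329 (1.57 ± 0.13, adjusted p = 2.08e-06) in ELF-153. HERV9-int, the internal part of that retrovirus, went from 98.4 ± 13.2 to 827 ± 19.4 (3.07 ± 0.18, adjusted p = 7.1e-08) and from 95.2 ± 20.1 to 442 ± 14.4 (2.23 ± 0.18, adjusted p = 2.02e-06). Of the families named in advance, LTR12D (2.78 ± 0.15), LTR12E (0.81 ± 0.16), HERVH-int (1.30 ± 0.29), LTR7 (1.05 ± 0.14), HERVK-int (1.91 ± 0.16), LTR5_Hs (0.85 ± 0.16), L1HS (0.75 ± 0.24), L1PA2 (1.02 ± 0.25), SVA_D (1.04 ± 0.18), THE1B (0.72 ± 0.26) and AluY (0.60 ± 0.13) also rose in UCSD-AML1, with adjusted p from 3.28e-08 to 0.049. In ELF-153 LTR12D (2.61 ± 0.15), HERVH-int (1.11 ± 0.29), LTR7 (0.52 ± 0.14), HERVK-int (1.51 ± 0.16), L1HS (1.39 ± 0.24), L1PA2 (1.91 ± 0.25), SVA_D (0.77 ± 0.18) and THE1B (0.79 ± 0.26) rose, with adjusted p from 1.43e-07 to 0.0496, and the change did not pass for LTR12E (0.39 ± 0.16), LTR5_Hs (0.44 ± 0.16) and AluY (−0.02 ± 0.13), with adjusted p from 0.0676 to 0.891; LTR12E, LTR7 and LTR5_Hs lay below 0 on the deposited repeat scaling, and THE1B at −0.2 with the mitochondrial covariate. MER57 and HSATII were not tested.

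Of 51 Alu families 36 rose in UCSD-AML1 and 1 rose and 1 fell in ELF-153, while with repeat-based scaling 2 rose and 1 fell and 1 rose and 7 fell. In camera the Alu class was up in UCSD-AML1 (adjusted p = 0.00213, and 0.729 with an estimated correlation) and down in ELF-153 (adjusted p = 5.15e-19, and 0.287 with an estimated correlation). In the other classes the families that rose and fell in UCSD-AML1 and rose and fell in ELF-153, with the counts on repeat-based scaling in brackets, numbered 27, 0, 12 and 0 of 43 ERVL (23, 0, 5 and 3); 43, 0, 19 and 0 of 77 MaLR (21, 1, 9 and 1); 174, 10, 112 and 6 of 410 other LTR (129, 31, 56 and 25); 5, 0, 6 and 0 of 7 HERVH/LTR7 (4, 0, 2 and 0); 4, 0, 1 and 0 of 5 HERVK/LTR5 (3, 0, 1 and 1); 4, 0, 4 and 0 of 6 SVA (1, 0, 0 and 0); 3, 0, 6 and 0 of 9 young L1 (3, 0, 6 and 0); 14, 1, 13 and 0 of 119 older L1 (12, 35, 4 and 4); 5, 0, 4 and 0 of 16 satellite (3, 0, 3 and 0); 1, 0, 0 and 0 of 6 MIR and other SINE (0, 1, 0 and 1); 24, 6, 18 and 0 of 208 DNA transposon (8, 78, 9 and 15); 2, 2, 3 and 1 of 33 L2, L3 and other LINE (0, 9, 2 and 1); 5, 3, 6 and 0 of 63 unclassified (3, 14, 1 and 1). With repeat-based scaling the median of DNA transposons went from 0.05 to −0.32 in UCSD-AML1 and from 0.47 to −0.03 in ELF-153, that of older L1 from 0.12 to −0.26 in UCSD-AML1, that of HERVK/LTR5 from 0.47 to −0.03 in ELF-153, and that of MIR from 0.26 to −0.12 and from 0.25 to −0.24. The median of L2 and L3 went from 0.10 to −0.28 in UCSD-AML1.

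The families with the largest rises were HERV-Fc2-int, which went from 0 ± 0 to 178 ± 52.3 scaled reads, and LTR14A (4.81 ± 0.38, adjusted p = 1.8e-06) in UCSD-AML1. In ELF-153 they were HERV-Fc1-int, which went from 1.02 ± 1.77 to 363 ± 36.8 and HERV-Fc2-int, from 0.373 ± 0.647 to 151 ± 10.5. The largest falls were of Helitron2Na_Mam (−2.35 ± 0.58, adjusted p = 0.00794) in UCSD-AML1 and of LTR21A (−0.97 ± 0.15, adjusted p = 0.000773) in ELF-153. Of 1063 families 357 rose and 22 fell in UCSD-AML1, and 214 rose and 8 fell in ELF-153, with medians of 0.43 and 0.55. The share of retained-intron transcripts in protein-coding reads went from 6.13 ± 0.35% to 7.17 ± 0.21% in UCSD-AML1 and from 5.83 ± 0.12% to 6.43 ± 0.06% in ELF-153 (not tested). The counts of rises and falls were 491 and 53 in UCSD-AML1 and 623 and 16 in ELF-153 with a replicate block, 497 and 46, then 55 and 1, with only the 6 libraries of the line, 248 and 207, then 56 and 23, with the mitochondrial covariate, 551 and 30, then 114 and 13, without the far libraries, and 220 and 170, then 106 and 59, with repeat-based scaling. Leaving out 1 library gave 228 (DAC 1) to 317 (DAC 2) rises and 9 (untreated 1) to 28 (DAC 3) falls in UCSD-AML1 and 110 (DAC 2) to 494 (untreated 2) and 4 (DAC 3) to 9 (untreated 1) in ELF-153. With scaling on the repeats alone the medians of all families shifted by −0.37 and −0.5. Over that and 2 other scalings 48.4% to 56.4% of called families were higher in UCSD-AML1 against 94.2%, and 56.4% to 77.6% in ELF-153 against 96.4%. The difference between lines was positive for 15 and negative for 36 families, with 29.4% positive against 12.5% to 62% under those scalings and edgeR with gene-table TMM; the counts were 105 and 102 with repeat-based scaling, 59 and 177 with the mitochondrial covariate and 166 and 101 with a replicate block, and leaving out 1 library gave 7 (UCSD-AML1 DAC 1) to 28 (UCSD-AML1 DAC 3) positive and 13 (UCSD-AML1 DAC 1) to 50 (ELF-153 untreated 1) negative. It was largest for HERVE_a-int (3.24 ± 0.23, adjusted p = 1.72e-06) and most negative for LTR14A (−4.62 ± 0.54, adjusted p = 0.000327).

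**Figure D3:**
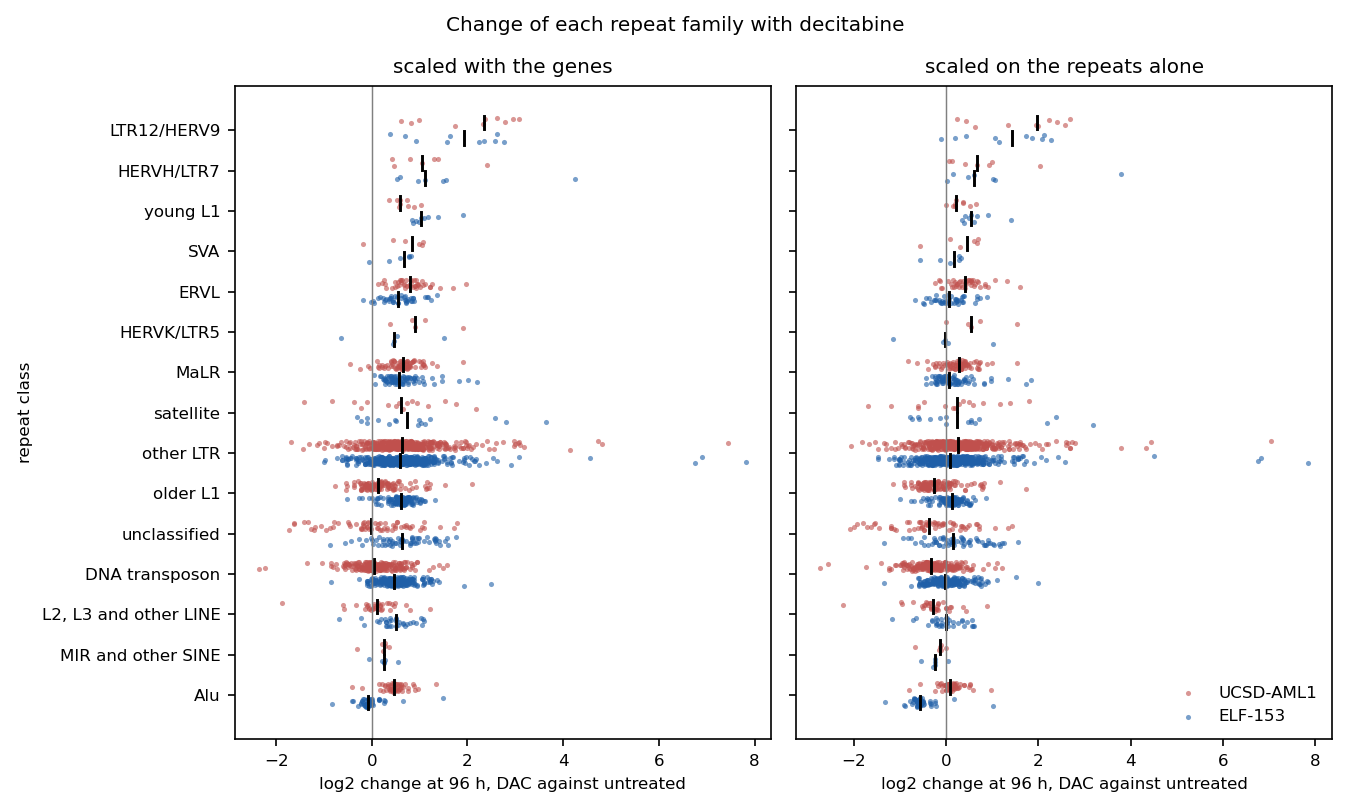
Log2 change with DAC at 96 h (x axis) of every tested repeat family in 15 classes, UCSD-AML1 in red and ELF-153 in blue, scaled with the genes in the left panel and on the repeats alone in the right. Black bars are class medians, which for LTR12/HERV9 were 2.35 and 1.93 on the left and 1.97 and 1.43 on the right; medians that changed sign are in the text.

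Whether DAC changed any chromosome as a block was tested with camera over the autosomes and X. Genes of chromosome 22 were down in ELF-153 at 96 h (adjusted p = 0.0177, and 0.792 with an estimated correlation) and those of chromosome 19 up in UCSD-AML1 at 144 h (adjusted p = 0.0165, and 0.82 with an estimated correlation). For the difference between lines at 96 h chromosome 13 was up (adjusted p = 0.0155) and chromosomes 16, 19 and 22 were down (adjusted p = 0.0065, 0.0014 and 0.00223). At 144 h chromosomes 4, 13 and X were up (adjusted p = 0.0368, 0.0135 and 0.0425) and 16, 19 and 22 down (adjusted p = 0.00667, 0.000877 and 0.005); no chromosome call held with an estimated correlation. The call in ELF-153 ended without untreated replicate 1 or DAC replicate 2 and that in UCSD-AML1 without DAC replicate 3.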

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

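Tests here with gene TMM scaling, GC trend removal or the mitochondrial rRNA share, and LTR12 counts on repeat-based scaling (itself planned), were chosen only after the result was seen. Results are given here where the DAC response differed between lines or harvests in a direct test, or where transcripts lay outside the gene tables. Between the lines, 3011 genes had a positive and 1533 a negative difference at 96 h, 3420 and 1741 at 144 h, and 15 and 36 among repeat families. With TMM scaling in edgeR the genes numbered 1984 and 1897, then 1961 and 2533, and on repeat-based scaling the families 105 and 102. Leaving out 1 library gave 2008 to 4513 and 1033 to 2478 at 144 h and 7 to 28 and 13 to 50 among repeats, leaving out the library of each group farthest in mitochondrial rRNA share 1855 and 823 at 96 h, that share as covariate 1734 and 755 at 144 h and 59 and 177 among repeats, and a replicate block 166 and 101 there. Of 100 drawn splits exchanging libraries, 1, 1 and 2 (the real one included) reached the real totals 4544, 5161 and 51. The highest other splits gave 3710, 3523 and 73. Of these splits 56 and 54 called as many lists as the real 4 and 5, and the highest called 16 and 15. Of the 55 and 53 others as large, 55 and 51 exchanged unequal numbers of treated libraries in the 2 lines, which leaves part of the DAC effect in the difference. Of 44 and 47 others with equal numbers 0 and 2 were as large (highest 2 and 5), but these mix treated and untreated libraries within groups, which widens the spread. Genes and repeats share these limits, so chance stays open for all.

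Interferon-stimulated genes were higher after DAC in ELF-153 than in UCSD-AML1 relative to untreated cells, with median differences of 2.70 at 96 h and 3.92 at 144 h (camera adjusted p = 1.46e-25 and 2.29e-30). TMM scaling shifts all genes nearly alike, so it could not decide on scaling as the cause. With it the median was 2.5 and 3.59 (lower quartiles of members 1.59 and 2.32). Against GC bias between libraries as the whole cause, it was 2.54 and 3.51 after each library's GC trend was removed, with lower quartiles of 1.47 and 2.46. A difference in biology between the lines stays open as a hypothesis, as do differences between cultures, since each group holds technical triplicates. The median level of the list was 450 in untreated UCSD-AML1 and 59.5 in untreated ELF-153 at 96 h, and 424 and 373 with DAC; at 144 h it was 628 and 54.4, and 394 and 566 with DAC. The larger change in ELF-153 thus started lower. Whether that bears on the response was not tested.

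LTR12 and HERV9 families rose with DAC, 10 of 10 in UCSD-AML1 and 9 in ELF-153. A general rise of reads from old repeats is argued against as the whole cause: 9 of 10 families in UCSD-AML1 and 7 in ELF-153 lay above the 95th percentile of 247 MIR, L2 and DNA transposon families (0.81 and 1.14, medians 0.06 and 0.47). Repeat-based scaling, which shifts all families nearly alike, left 8 and 7 families higher and cannot decide on scaling as the cause. Loss of methylation at these repeats may contribute, but methylation was not measured here. Reads that start in a repeat and reads of longer transcripts that run through one were not separated.

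After each library's GC trend was removed, camera called 0 chromosomes in the 4 comparisons within lines and the 2 between lines. Adjusted p was 0.98 for chromosome 19 in UCSD-AML1 at 144 h, whose excess median change went from 0.44 to 0.18 (gene interquartile ranges 1.38 and 1.4), and 0.987 for chromosome 22 in ELF-153 at 96 h, from −0.38 to −0.13 (gene interquartile ranges 1.15 and 1.09). Over the 23 chromosomes the Spearman correlation of that excess with GC content was 0.902 and 0.872 in UCSD-AML1, −0.859 and −0.758 in ELF-153 and −0.93 and −0.947 between lines, and 0.239, 0.383, −0.146, −0.028, −0.519 and −0.559 afterwards. GC bias between libraries may therefore account for the calls within lines. Between lines the excess of the called chromosomes, 0.44 to 0.52 at 96 h and 0.42 to 0.63 at 144 h in size, fell to 0.07 to 0.12 and 0.01 to 0.26, least for X (0.42 to 0.26). Biology that goes with GC content stays open.

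Single genes with a difference between lines at 96 h were GATA1 (2.92), HBG1 (3.26), HIST1H4C (9.6), IFI44L (8.25), KIT (2.97) and RSAD2 (3.92), and, near 0 in a group, CDKN2B (adjusted p = 7.34e-05) and SYNDIG1 (adjusted p = 7.61e-07). At 144 h they were DNMT3A (1.07), GATA1 (3.39), HBG1 (3.27), KIT (3.54), MYC (−1.34) and IFI44L (adjusted p = 2.24e-07). Camera's adjusted p for the line difference was 1.82e-08 and 5.36e-08 for cancer-testis antigens, 7.36e-07 and 4.04e-07 for germ-cell genes, 8.67e-08 and 5.25e-05 for cell cycle genes, and 0.0411 for T and NK cell markers at 144 h (0.186 with an estimated correlation). The filter bears on the antigen and germ-cell values. Of transcripts whose identifiers matched no annotated gene, 319 and 250 were called with DAC at 96 h and 381 and 334 at 144 h, in UCSD-AML1 and ELF-153.

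Between harvests 7 genes had a higher and 13 a lower change in UCSD-AML1, among them CHAC1 (−4.21), ULBP1 (−4.33), SLC7A11 (−2.97) and SIK1 (1.91). In ELF-153 8 had a higher change, among them THBS1 (2.09), and, near 0 in a group, F2RL2 and MECOM (adjusted p = 0.0241 and 0.0207). The counts in UCSD-AML1, then ELF-153, were 0 and 3, then 2 and 0, with a replicate block (without SIK1, F2RL2 and MECOM), 29 and 40, then 23 and 0, in DESeq2, 24 and 152, then 41 and 21, with the mitochondrial rRNA share as covariate and 42 and 249, then 690 and 666, without the library of each group farthest in it. Of the drawn splits 10 and 10 of 100 gave totals as large as the real 20 and 8, and the highest gave 6631 and 7107. The 9 and 9 others as large all exchanged treated for untreated libraries in unequal numbers at the 2 harvests. Of 43 and 41 with equal numbers 0 and 0 were as large (highest 0 and 1). Whether chance can be excluded stays open for the same reasons, as do different aligners and changed untreated cultures.

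Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. The others mix the groups, which widens the spread and keeps part of the effect, so chance stays open. Called genes numbered 7058, 5913, 8059 and 6691 (UCSD-AML1 and ELF-153 at 96 h, then 144 h). The highest other split gave 2, 0, 0 and 1 (1, 1, 1 and 1 as large, the real one included). For the untreated lines the counts were 10195 and 8903 against 0 and 0 (1 and 1 as large) and for repeat families 379 and 222 against 0 and 0 (1 and 1). For gene lists they were 16, 14, 14 and 16 against 9, 14, 14 and 15 (1, 2, 2 and 1), and for chromosomes in ELF-153 at 96 h and UCSD-AML1 at 144 h 1 and 1 against 3 and 7 (6 and 3).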

How the results depend on the processing

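The tests with edgeR with TMM, the pseudocounts 0.5 and 8, TMM scaling in limma, sums without retained-intron and processed transcripts, the mitochondrial rRNA share as covariate, removal of the GC trend, leaving out the libraries farthest in that share, and the deposited element scaling were chosen only after the result was seen; the other alternatives, the lists and the comparisons were set before the data were examined. Of gene values under all alternatives 2919 kept their direction and side of 0.05, 97 lost and 14 gained the call and 36 changed sign; for repeat families the numbers were 595, 65, 5 and 19, and for lists 2101, 74, 135 and 0. Counts outside a 1.5-fold range of the limma count, and log2 changes whose sign turned, follow by alternative; the cause was not tested. Of the values whose sign turned, LTR7 in ELF-153 and THE1B in ELF-153 passed the limma test, and CDKN2B and MECOM lay near 0 in a group.

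With edgeR with RLE there were 2163 positive line differences at 144 h and 4 higher time differences in UCSD-AML1, and the sign turned for CD34 (0.09) and DNMT3A (0) in UCSD-AML1 at 96 h. With edgeR with TMM there were 1984 positive line differences at 96 h, 1961 positive line differences at 144 h and 8 lower time differences in UCSD-AML1, and the sign turned for CD34 (0.11) and DNMT3A (0.02) in UCSD-AML1 at 96 h and GATA2 (−0.02) in ELF-153 at 144 h. With DESeq2 there were 29 higher and 40 lower time differences in UCSD-AML1 and 23 higher time differences in ELF-153, and the sign turned for CD34 (0.09) and DNMT3A (0) in UCSD-AML1 at 96 h. With limma-voom there were 2625 negative line differences at 144 h and 2 higher time differences in ELF-153, and the sign turned for CD34 (0.13) and DNMT3A (0.03) in UCSD-AML1 at 96 h and GATA2 (0) in ELF-153 at 144 h. With a test against a fold of 1.5 there were 1670 genes higher and 1388 lower in UCSD-AML1 at 96 h, 1669 genes higher and 693 lower in ELF-153 at 96 h, 1767 genes higher and 2139 lower in UCSD-AML1 at 144 h and 1923 genes higher and 1216 lower in ELF-153 at 144 h. With TMM scaling in limma there were 2837 negative line differences at 144 h and 11 higher time differences in UCSD-AML1, and the sign turned for CD34 (0.12) and DNMT3A (0.01) in UCSD-AML1 at 96 h and GATA2 (−0.01) in ELF-153 at 144 h. With sums without retained-intron and processed transcripts there were 3 higher time differences in UCSD-AML1 and 5 higher time differences in ELF-153, and the sign turned for CD34 (0.15) in UCSD-AML1 at 96 h. With the mitochondrial rRNA share as covariate there were 2124 genes higher and 1346 lower in ELF-153 at 96 h, 1880 genes higher and 2624 lower in untreated ELF-153 at 96 h, 1734 positive and 755 negative line differences at 144 h, 2237 genes lower in untreated ELF-153 at 144 h, 24 higher and 152 lower time differences in UCSD-AML1, 41 higher and 21 lower time differences in ELF-153, 207 repeat families lower in UCSD-AML1, 56 repeat families higher and 23 lower in ELF-153, 59 positive and 177 negative repeat line differences, 1 chromosome in UCSD-AML1 at 96 h, 0 chromosomes in ELF-153 at 96 h and 12 gene lists between lines at 144 h, and the sign turned for CDKN2B (−0.12) and MYC (0.07) in UCSD-AML1 at 96 h, KIT (−1.12), MECOM (−0.49), AluY (0.27), Helitron2Na_Mam (−0.83), LTR14A (−0.74) and THE1B (−0.2) in ELF-153 at 96 h and KIT (−1.59) in ELF-153 at 144 h. With the GC trend removed from each library there were 1991 positive line differences at 96 h, 22 higher and 41 lower time differences in UCSD-AML1, 19 higher and 3 lower time differences in ELF-153, 9 gene lists between lines at 96 h, 0 chromosomes in ELF-153 at 96 h, 13 gene lists between lines at 144 h and 0 chromosomes in UCSD-AML1 at 144 h, and the sign turned for CD34 (0.05) and GATA2 (−0.19) in UCSD-AML1 at 96 h and GATA2 (−0.21) and MYC (−0.06) in UCSD-AML1 at 144 h. With the library of each group farthest in mitochondrial rRNA share left out there were 1855 positive and 823 negative line differences at 96 h, 2795 negative line differences at 144 h, 42 higher and 249 lower time differences in UCSD-AML1, 690 higher and 666 lower time differences in ELF-153, 551 repeat families higher in UCSD-AML1, 114 repeat families higher and 13 lower in ELF-153 and 184 negative repeat line differences, and the sign turned for GATA2 (−0.07) in UCSD-AML1 at 96 h, KIT (−0.32), AluY (0.13), Helitron2Na_Mam (−0.28) and LTR14A (−0.25) in ELF-153 at 96 h and GATA2 (−0.05) in ELF-153 at 144 h. With a block for replicate number there were 3015 genes higher and 2510 lower in untreated ELF-153 at 144 h, 0 higher and 3 lower time differences in UCSD-AML1, 2 higher time differences in ELF-153, 53 repeat families lower in UCSD-AML1, 623 repeat families higher and 16 lower in ELF-153 and 166 positive and 101 negative repeat line differences. With no filter beyond 1 read there were 3 higher time differences in UCSD-AML1 and 1 lower time differences in ELF-153. The change of KIT in ELF-153 at 144 h with the mitochondrial rRNA share as covariate passed the test (adjusted p = 0.00177, range over its alternatives 0.00177 to 1).

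With pseudocount 8 there were 30 lower time differences in UCSD-AML1 and 31 higher time differences in ELF-153. With library sizes and TMM factors from the elements alone there were 220 repeat families higher and 170 lower in UCSD-AML1, 106 repeat families higher and 59 lower in ELF-153 and 105 positive and 102 negative repeat line differences, and the sign turned for LTR12E (−0.11), LTR14A (−0.26) and LTR5_Hs (−0.06) in ELF-153 at 96 h. With gene-table library sizes without TMM factors there were 81 repeat families higher and 76 lower in UCSD-AML1, 66 repeat families higher and 19 lower in ELF-153 and 31 positive and 19 negative repeat line differences, and the sign turned for LTR14A (−0.13) in ELF-153 at 96 h. With DESeq2 with gene-table size factors there were 325 repeat families higher and 14 lower in ELF-153 and 36 positive and 81 negative repeat line differences. With only the 6 libraries of the line there were 46 repeat families lower in UCSD-AML1 and 55 repeat families higher and 1 lower in ELF-153. With edgeR with gene-table TMM there were 14 repeat families lower in UCSD-AML1 and 105 negative repeat line differences. With the deposited element scaling there were 187 repeat families higher and 199 lower in UCSD-AML1, 92 repeat families higher and 71 lower in ELF-153 and 120 positive and 98 negative repeat line differences, and the sign turned for LTR12E (−0.16), LTR14A (−0.29), LTR5_Hs (−0.11) and LTR7 (−0.03) in ELF-153 at 96 h. With an estimated correlation there were 7 gene lists in UCSD-AML1 at 96 h, 0 chromosomes in ELF-153 at 96 h, 6 gene lists in UCSD-AML1 at 144 h and 0 chromosomes in UCSD-AML1 at 144 h. With fry there were 25 gene lists in UCSD-AML1 at 96 h, 25 gene lists in ELF-153 at 96 h, 18 gene lists between lines at 96 h, 24 gene lists in UCSD-AML1 at 144 h, 27 gene lists in ELF-153 at 144 h and 18 gene lists between lines at 144 h. With only genes with a mean of at least 1 CPM there were 1 chromosome in UCSD-AML1 at 96 h. With a Fisher test of the share of genes higher there were 3 chromosomes in UCSD-AML1 at 96 h, 4 chromosomes in ELF-153 at 96 h, 12 chromosomes in UCSD-AML1 at 144 h and 3 chromosomes in ELF-153 at 144 h. With calls of at least 2-fold there were 603 genes lower in both UCSD-AML1 96 h and ELF-153 96 h, 897 genes lower in both UCSD-AML1 144 h and ELF-153 144 h and 1082 genes lower in both ELF-153 96 h and ELF-153 144 h.

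Leaving out 1 library at a time, with the line (where both are compared), treatment and replicate number left out in brackets, gave 2008 (ELF-153 DAC 2) to 4513 (ELF-153 untreated 1) positive line differences at 144 h, 1033 (ELF-153 untreated 2) to 2478 (ELF-153 untreated 1) negative line differences at 144 h, 0 (untreated 96 h 1) to 11 (untreated 144 h 3) higher time differences in UCSD-AML1, 3 (untreated 144 h 2) to 21 (untreated 144 h 3) lower time differences in UCSD-AML1, 4 (DAC 96 h 3) to 14 (untreated 144 h 1) higher time differences in ELF-153, 0 (untreated 96 h 2) to 2 (untreated 144 h 1) lower time differences in ELF-153, 228 (DAC 1) to 317 (DAC 2) repeat families higher in UCSD-AML1, 9 (untreated 1) to 28 (DAC 3) repeat families lower in UCSD-AML1, 7 (UCSD-AML1 DAC 1) to 28 (UCSD-AML1 DAC 3) positive repeat line differences, 13 (UCSD-AML1 DAC 1) to 50 (ELF-153 untreated 1) negative repeat line differences, 110 (DAC 2) to 494 (untreated 2) repeat families higher in ELF-153, 4 (DAC 3) to 9 (untreated 1) repeat families lower in ELF-153, 0 (untreated 1) to 1 (DAC 3) chromosomes in UCSD-AML1 at 96 h, 0 (untreated 1) to 1 (untreated 2) chromosomes in ELF-153 at 96 h, 9 (untreated 1) to 14 (untreated 3) gene lists in UCSD-AML1 at 144 h, 4 (UCSD-AML1 untreated 3) to 10 (ELF-153 untreated 2) gene lists between lines at 144 h and 0 (DAC 3) to 1 (untreated 1) chromosomes in UCSD-AML1 at 144 h. Log2 changes whose sign turned in this series were CD34 (−0.14 to 0.14), CDKN2B (0 to 0.49) and GATA2 (−0.02 to 0.14) in UCSD-AML1 at 96 h, GATA2 (−0.07 to 0.08) and KIT (−0.08 to 1.03) in ELF-153 at 144 h and AluY (−0.12 to 0.13), Helitron2Na_Mam (−0.05 to 0.96) and LTR14A (−0.11 to 0.65) in ELF-153 at 96 h.

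In data simulated from these libraries, limma recovered 83.3%, 92.4%, 84.8% and 87.9% of genes changed 4-fold and 28.4%, 25.4%, 10.4% and 7.5% of genes changed 2-fold (UCSD-AML1 and ELF-153 at 96 h, then at 144 h), and 45.5% and 33.3% of 4-fold line differences. Within groups, the first component held 33.7% of the variance at 96 h and 40.5% at 144 h, and went with the mitochondrial rRNA share over 12 libraries (r = 0.948, exact permutation p = 0.00386; rho = 0.86, exact permutation p = 0.0108; r = 0.885 without the 2 farthest; at 144 h r = 0.971, p = 0.00231, rho = 0.958, p = 0.00231 and r = 0.953, exact, two-sided).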

Other observations

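The tests in this part were all chosen only after the result was seen. Across processed pseudogenes with a tested parent gene, which are not independent replicates, the log2 change with DAC had a Spearman correlation with that of the parent of 0.527, 0.542, 0.465 and 0.541 (UCSD-AML1 and ELF-153 at 96 h, then at 144 h). Reads of parent transcripts placed on pseudogenes were not separated from transcription of the pseudogenes.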
